A study of Mus musculus with 26 samples.

How the data were processed

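Bulk RNA sequencing of mouse liver tumours and control livers was used, with 26 libraries in 4 groups. Per the labels' protocols, RNA was extracted from frozen tissue with an organic reagent and a column kit, treated with DNase and made into libraries with a Nugen Ovation kit. The values are whole-number counts of reads per gene symbol in a single table, as deposited by the authors, with no normalization. Per the submitters' processing notes the genome build was mm10. The aligner, the counting program, its strand setting and the gene annotation are not given in the sources used here. The table had 35976 genes or gene models with 0 duplicated symbols, and every column of values belonged to 1 of the 26 libraries. Reads that fit near-identical genes or overlapping genes could have been split or dropped in the counting, so values of the major urinary protein, alpha-1-antitrypsin, cytochrome P450, glutathione S-transferase and H2 families are uncertain.

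Groups were taken from the genotype labels. Several titles share an animal number (CAB28 in 2 libraries, GAB242 and GAB294 in 3 each), which was read from the titles as the same animal. The deposited counts were summed over libraries with the same number, giving 9 Cyp1a2_CA, 5 Gls2_CA and 6 WT animals, so p-values measure the spread between animal numbers. The Spearman correlation of deviations from the group mean was 0.31 for the pair of libraries of CAB28 and had a median of 0.15 over 6 pairs in Gls2_CA (lowest -0.08), and pairs from different animals reached 0.79 in Cyp1a2_CA. No 2 libraries were as close as sampling noise alone would make them, so none was counted as a duplicate. The letter after the hyphen of a title (S, M or L) is not explained in the labels and was used only as a covariate in an alternative. The gene list test with that covariate counted every library as a replicate.

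Each pair of groups was fitted alone with edgeR 4.0.16 in R 4.3.3: low counts were removed with filterByExpr, libraries were scaled with TMM, a robust quasi-likelihood model was fitted and tested, and p-values were adjusted by Benjamini-Hochberg with a threshold of 0.05. All adjusted p-values of genes are from edgeR unless another tool is named. Genes are said to rise, fall or pass only where this adjusted p was under 0.05. Levels are CPM, the deposited counts relative to TMM-scaled library totals in the usual unit, as mean ± SD over animals. A fold change against a group with 0 counts was computed against a floor of 3 counts over the group (0.0318 CPM in WT).

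For 30 gene lists with 348 symbols, of which 346 were found (1 under an older symbol), members past the threshold were counted, adjusted over all genes and adjusted over the list alone. The camera test of limma 3.58.1 compared each list with the other genes on log2 CPM with a prior count of 2 and a preset correlation of 0.01, adjusted over the lists, and was repeated with an estimated correlation. The fry test asks instead whether the genes of a list move 1 way on balance. Adjusted p-values given for lists are from camera. The median, mean and test direction of a list differed in sign in 7, 4 and 3 lists of the 3 comparisons (Cyp1a2_CA against Gls2_CA, Cyp1a2_CA against WT, Gls2_CA against WT), none of which was called.

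The comparisons, lists, tests and the rule for the genes named were fixed before the data were examined. In each comparison the rule took the 8 largest rises and 8 largest falls among genes past the threshold with a mean of at least 5 CPM in the higher group, every animal of the higher group above the median animal of the lower group and the reverse, leaving out models without a symbol. It also took up to 4 measured members of each list with the smallest p, and Ctnnb1, Arid2, Cyp1a2, Gls2 and Nnt always. The text names part of these, and 1 further result is not reported here. Dnah1, Pecam1 and the genes that describe the libraries standing apart were chosen after their values were seen. Coordinates, exon lengths and GC content came from GENCODE M21 on the mm10 assembly by symbol, which matched 27278 of 35976 entries (75.8%). For the offset on length and GC, 90.1% of the genes tested between Cyp1a2_CA and WT and 92.3% of those between Gls2_CA and WT had a value.

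The alternatives were RLE and upper-quartile factors, no filter and a stricter filter, every library as a replicate, the first library of each animal number, all 3 replicated groups in 1 fit, DESeq2 1.42.0, limma-voom with quality weights, limma-voom with the animal number as a random effect, a fit without sex-related, immunoglobulin and haemoglobin genes, and leaving out each animal. Chosen after seeing the data were fits without the libraries with Ttn above 1000 CPM, with an offset for gene length and GC, with tumour counts thinned to the median WT total, and the gene list test with the title letter as a covariate. The steps were tested on counts simulated from the means and library sizes of these samples with 100 genes changed 2-fold and 100 changed 4-fold. The shares recovered were 12% and 57% for Cyp1a2_CA against Gls2_CA (3 false calls among 16833 genes), 29% and 66% for Cyp1a2_CA against WT (1 among 16533) and 28% and 84% for Gls2_CA against WT (3 among 14808). Other splits of the animals were drawn 60 times per comparison, the real one included.

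Depth differed by group, and the lowest tumour total was 2.18 times the highest WT total. The WT libraries therefore give less precise values for low genes. Scaling moved the median log2 fold change of all genes from 0.17 with TMM to -0.05 with upper-quartile factors for Cyp1a2_CA against WT and from 0.14 to -0.09 for Gls2_CA against WT. The single Cyp1a2_C library entered no test. Plots were drawn with Python 3.11.15 and matplotlib 3.10.9.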

Results

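RNA was sequenced from 20 mouse liver tumour libraries and 6 control liver libraries, and the deposited table gave reads per gene symbol for all 26. Tumours were induced by tamoxifen on postnatal day 28 with a tamoxifen-dependent Cre recombinase (CreERT2) under the promoter of Cyp1a2, a cytochrome P450 gene of hepatocytes around the central vein, or of Gls2, a glutaminase gene of hepatocytes around the portal vein. Cre acted on a Ctnnb1 allele that loses exon 3, which encodes the part of beta-catenin that marks it for degradation, and in all but 1 animal also on both copies of Arid2, a subunit of the PBAF chromatin remodelling complex. Tumour mice were followed for 6 to 12 months, and WT mice, with no tamoxifen day in the labels, for up to 12. The groups were Cyp1a2_CA (both alleles under Cyp1a2-CreERT2, 10 libraries from 9 animal numbers), Gls2_CA (both alleles under Gls2-CreERT2, 9 libraries from 5 animal numbers), Cyp1a2_C (the Ctnnb1 allele alone under Cyp1a2-CreERT2, 1 library) and WT (6 libraries of wild-type liver from mice given Cre by adeno-associated virus). Tumour mice were mixed C57BL/6J and Swiss Webster and WT mice were C57BL/6J, so strain, virus, tamoxifen, follow-up and tumour genotype changed together. Libraries whose titles share an animal number were summed, and n counts animal numbers.

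Total counts per library lay between 37051941 and 49254470 in Cyp1a2_CA, between 36992043 and 42865787 in Gls2_CA and between 13486530 and 16975288 in WT, and was 41038144 in Cyp1a2_C. No tumour library overlapped the WT libraries in depth. The mitochondrial share of counts was 8.90 to 11.1% in WT and 1.43 to 6.73% in the 20 tumour libraries, and the median ribosomal protein gene had 90.8 to 108 CPM (counts scaled by library total) in WT and 33.5 to 74.7 in tumours. The first principal component (48.9% of the variance of the 2000 most variable genes) separated 4 tumour libraries from the other 22, and the second (20%) separated WT from the other tumours. The 4 were CAB44-L and CAB225-L (Cyp1a2_CA replicates 6 and 8), GAB235-S (Gls2_CA replicate 3) and CB6-L (Cyp1a2_C), and in them Ttn, the gene of the muscle protein titin, was at 8668 to 30171 CPM against at most 92.9 in the other 16 tumour libraries and 2.21 in WT.

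**Figure D1:**
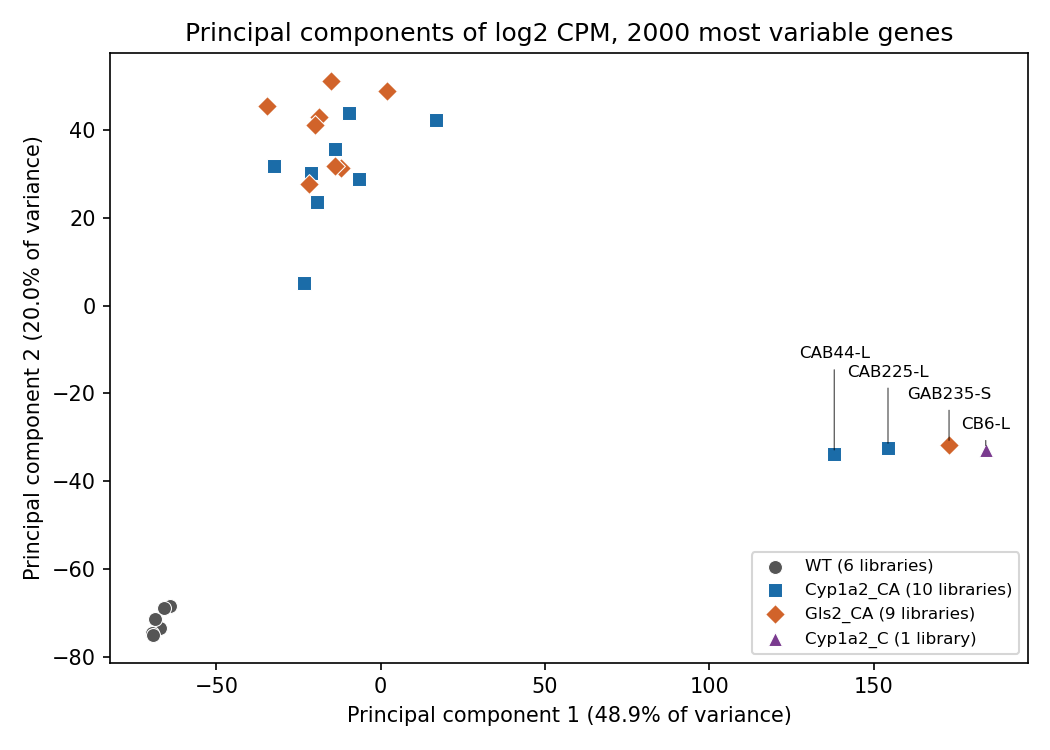
First 2 principal components of log2 CPM over the 2000 most variable genes, 1 point per library, with the share of variance on each axis and the groups by colour and shape. CAB44-L, CAB225-L, GAB235-S and CB6-L lie to the right of all other libraries, and the 6 WT libraries lie together at the lower left.

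The genes named by the genotypes were examined first. Arid2 (chromosome 15, 96287518 to 96404992, mm10) was at 67.2 ± 4.33 CPM in WT (SD, n = 6), 31.1 ± 4.05 in Cyp1a2_CA (n = 9) and 36.3 ± 8.46 in Gls2_CA (n = 5). It fell in both tumour groups against WT, with log2 fold changes of -1.18 (SE 0.105, adjusted p = 6.2e-08) and -0.97 (SE 0.166, adjusted p = 0.00023), or -2.23 and -2.04 with an offset for gene length and GC. All 19 libraries of these groups (23.4 to 47.1 CPM) lay below the lowest WT library (60.1 CPM), and so did the Cyp1a2_C library at 42.5 CPM, whose label names no Arid2 allele and which held Xist beside Y-linked transcripts, so that its identity is open. Counts of the whole gene do not show which exons were lost. Ctnnb1 (chromosome 9, 120929216 to 120960507) was at 138 ± 48.8 CPM in Cyp1a2_CA, 134 ± 106 in Gls2_CA and 164 ± 10.3 in WT. Neither difference from WT passed with edgeR (log2 fold changes -0.31, adjusted p = 0.19, and -0.34, adjusted p = 0.43), and a gene total is not a measure of the loss of exon 3. GAB235 had 323 CPM of Ctnnb1 and the next Gls2_CA animal 98.9. Without GAB235 (Gls2_CA replicate 3) the Gls2_CA value was -1.04 (adjusted p = 2.0e-06), and without the libraries with Ttn above 1000 CPM the Cyp1a2_CA value was -0.57 (adjusted p = 0.0026). With all animals the Cyp1a2_CA value passed with upper-quartile factors (-0.53, adjusted p = 0.030), limma-voom with quality weights (-0.54, 0.00035) and the length and GC offset (-0.70, 0.0012). The Gls2_CA value passed with limma-voom, with quality weights (-1.04, adjusted p = 1.5e-05) and with a random effect (-0.74, 0.029).

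Both driver genes were lower in tumours of either driver than in WT. Cyp1a2 (chromosome 9, 57676937 to 57683703) was at 847 ± 74.9 CPM in WT, 197 ± 85.5 in Cyp1a2_CA (log2 fold change -2.19, adjusted p = 1.4e-05) and 388 ± 213 in Gls2_CA (-1.23, adjusted p = 0.0041). Gls2 (chromosome 10, 128194457 to 128210004) was at 211 ± 18 CPM in WT, 26.2 ± 21.1 in Cyp1a2_CA (-3.08, adjusted p = 0.00019) and 14.2 ± 11.8 in Gls2_CA (-3.98, adjusted p = 5.6e-05). The Cyp1a2_C library held 0.374 CPM of Cyp1a2 and 3.09 CPM of Gls2. Nnt (chromosome 13, 119335448 to 119408997), which carries a deletion in C57BL/6J, was at 51.9 ± 16.8 CPM in WT, 27.5 ± 12.3 in Cyp1a2_CA (adjusted p = 0.0067) and 33.7 ± 12.3 in Gls2_CA (log2 fold change -0.73, adjusted p = 0.038). The Gls2_CA value did not pass under 13 of the alternatives tried (-0.52 to -0.73) and was -1.33 with the length and GC offset (adjusted p = 0.0025).

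**Figure D2:**
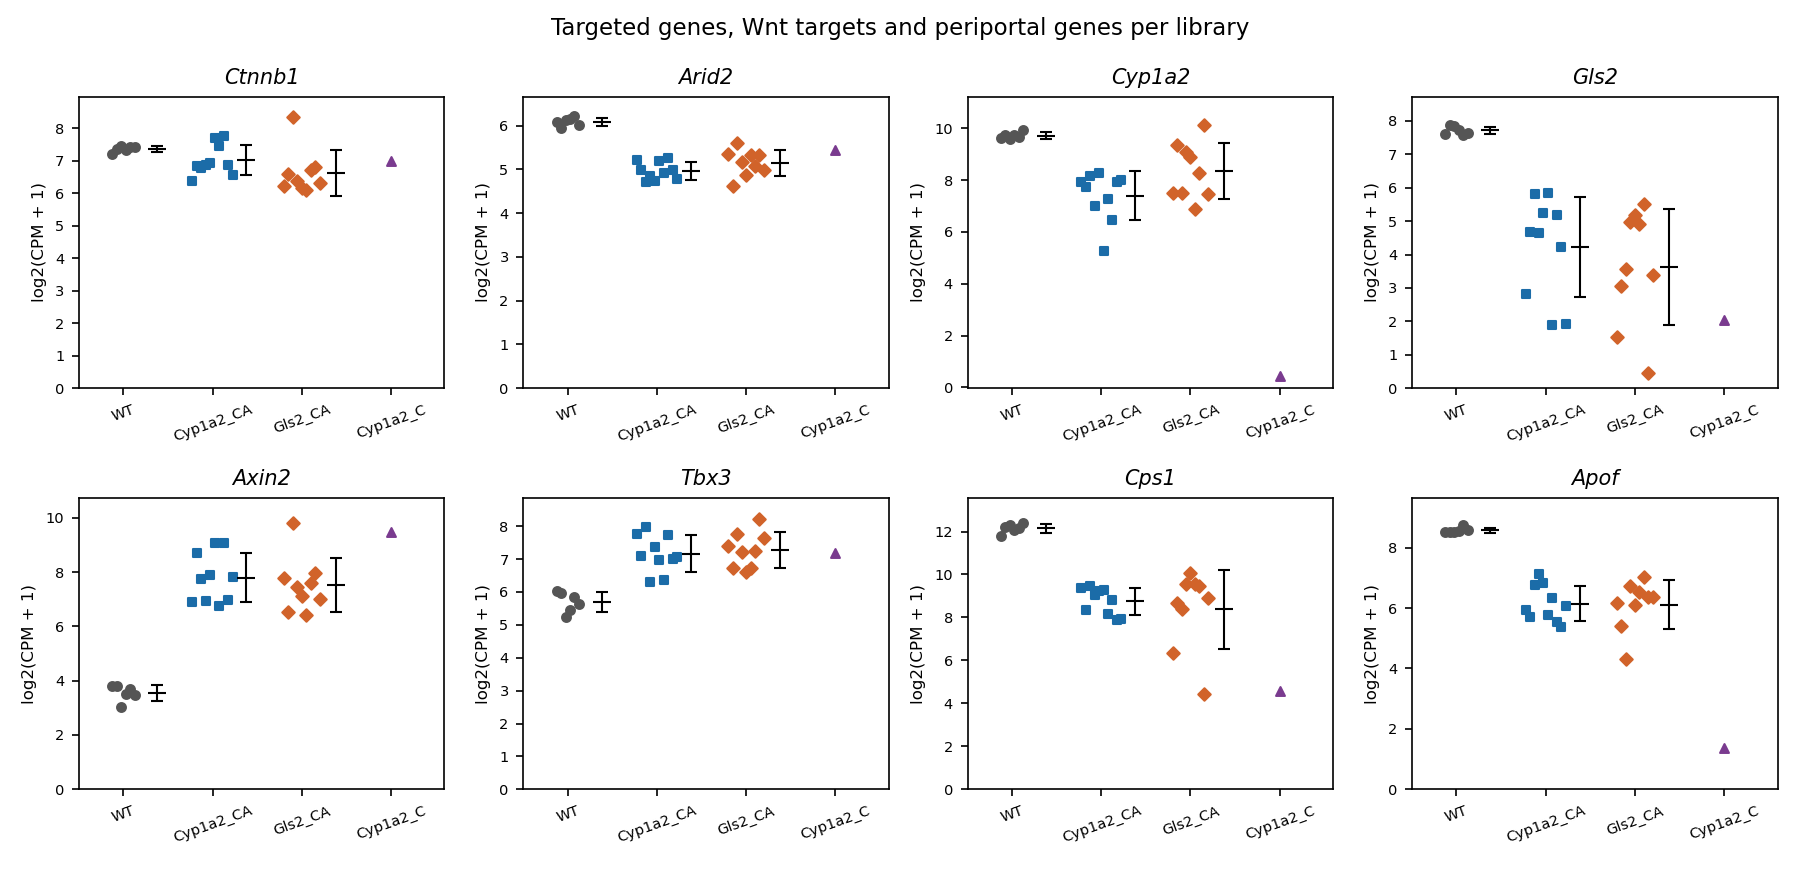
Level of the targeted and driver genes, 2 Wnt targets (Axin2, Tbx3), Cps1 of the urea cycle and Apof of the periportal list, as log2(CPM + 1) on the vertical axis, 1 point per library. The horizontal bar and whiskers are the mean and SD over the libraries of a group, several of which come from 1 animal number in Gls2_CA. Arid2, Gls2, Cps1 and Apof lie below the WT libraries in every library of both tumour groups, and Axin2 and Tbx3 lie above them in every such library.

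The comparison of Cyp1a2_CA with WT asks how tumours started from cells around the central vein differ from control liver. Most targets of Wnt/beta-catenin signalling and most proliferation genes rose, while all periportal and urea cycle genes listed fell. Axin2, a feedback inhibitor of the Wnt pathway (chromosome 11, 108920349 to 108950783), was at 276 ± 173 CPM against 11 ± 2.19 in WT, 24.1-fold higher (log2 fold change 4.59, SE 0.459, adjusted p = 2.6e-07), and lay above every WT animal in 9 of 9. Mki67, a marker of dividing cells, was 34.4-fold higher (5.10, SE 0.465, adjusted p = 9.2e-08). Cps1, the first enzyme of the urea cycle, was at 461 ± 192 CPM against 4601 ± 679 (-3.39, SE 0.267, adjusted p = 1.6e-08) and lay below every WT animal in 9 of 9. Of 16841 genes tested, 11941 passed, 6442 higher and 5499 lower, and 9087 of these changed by over 2-fold. The balance turned with upper-quartile factors (5592 higher and 6260 lower).

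Of 18 Wnt/beta-catenin targets, 16 rose and 0 fell, with a median log2 fold change of 2.24. Beside Axin2, Rnf43, which removes Wnt receptors, was higher by 1.81 (adjusted p = 9.2e-07), the transcription factor Tcf7 by 2.25 (4.2e-05) and Tbx3 by 1.53 (2.7e-05). With the length and GC offset 13 of the 18 rose, and the log2 fold changes of Axin2, Rnf43 and Tbx3 were 3.94, 0.97 and 0.81. All 14 periportal genes fell (median -2.69), among them Apof (382 ± 22.2 CPM in WT and 71.4 ± 30.4 in tumours), an apolipoprotein, and Igfals (-2.34, adjusted p = 1.1e-08), which carries insulin-like growth factors in blood. All 8 urea cycle genes fell (median -1.84), with Arg1, which releases urea from arginine, at -4.20 (adjusted p = 1.7e-07). In the proliferation list 17 of 20 rose and 2 fell, and Cenpf, a kinetochore protein, was 49.3-fold higher (54.8 ± 23.1 CPM against 1.05 ± 0.209). With the length and GC offset the log2 fold change of Cenpf moved from 5.62 to 4.29 and that of Mki67 from 5.10 to 4.10. Against other genes these 4 lists were called with a preset correlation of 0.01 (adjusted p = 0.011, 0.00062, 0.0038 and 0.0011), and none was with an estimated correlation (adjusted p = 0.74).

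Of 12 hepatocyte identity genes 8 fell and 0 rose, with Alb (albumin) at 11793 ± 8008 CPM against 58612 ± 8919 and Fgb (a fibrinogen chain) at -2.44 (adjusted p = 2.4e-07). Of 10 genes of bile acid synthesis and transport 7 fell, and Slc27a5, which activates bile acids for conjugation, was 7.12-fold lower (adjusted p = 2.9e-08). Of 9 male-biased liver genes 8 fell, led by Selenbp2 (17 ± 21.7 CPM against 1052 ± 364, adjusted p = 9.0e-06) and including Slco1a1, an organic anion transporter (-3.54, adjusted p = 6.1e-05). Mup14, of the major urinary protein family whose near-identical copies share reads, was lower by the most of the genes named here (-7.56, adjusted p = 4.0e-06, or -8.68 without CAB28). These 3 lists were called with the preset correlation (adjusted p = 0.027, 0.027 and 0.016) and not with an estimated one (adjusted p = 0.74 each). The first 2 were no longer called with an offset for gene length and GC (adjusted p = 0.076 each) or without the libraries with Ttn above 1000 CPM (0.066 and 0.057). Their median log2 fold changes were -0.83 and -1.59 with all libraries, -1.24 and -1.34 with the offset and -0.62 and -1.39 without those libraries.

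Of 16 glutathione S-transferases, detoxifying enzymes of which several are near-identical copies that can share reads, 10 rose and 3 fell. Gstm4 was 7.07-fold higher (adjusted p = 6.2e-06) and Gstp1 was 8.49-fold lower (4.7e-07). Of 16 pericentral metabolism genes 3 rose and 10 fell, the latter including Cyp1a2 itself. In gluconeogenesis 5 of 7 fell, with Pck1 at 69.8 ± 42.6 CPM against 1532 ± 570 (adjusted p = 7.2e-07). Thrsp, a regulator of fat synthesis, was 35.1-fold lower (adjusted p = 8.7e-07) in a lipogenesis list with 3 rises and 4 falls, and Hmgcs1, of cholesterol synthesis, was 4.81-fold higher (6.6e-05) in a list with 3 rises and 3 falls. Of the MHC class I presentation genes 1 of 8 rose and 6 fell. H2-K1 was higher by 1.12 (adjusted p = 2.1e-05) and H2-D1, its near relative in which strain variants can move reads, was lower (-2.08, adjusted p = 3.9e-08). In acute phase 1 of 12 rose and 8 fell, in fatty acid oxidation 5 of 14 rose and 7 fell, in glycolysis 4 of 14 rose and 4 fell, in antioxidant and iron handling 8 of 16 rose and 5 fell, and in interferon response 1 of 13 rose and 3 fell. Of 5 sex-chromosome genes 2 rose and 0 fell. None of the lists in this paragraph was called. Adjusted over the list alone, the counts of this comparison differed from those over all genes in 3 lists, interferon response (0 rose and 0 fell), oncofetal genes (12 rose) and cholangiocyte markers (2 rose).

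Of 13 measured oncofetal genes, which are active in fetal liver, 11 rose and 0 fell, although the list was not called (adjusted p = 0.097). Igf2, a fetal growth factor, was at 5129 ± 13646 CPM against 0.358 ± 0.221 (log2 fold change 13.71, adjusted p = 0.0017) and H19, its imprinted neighbour, at 2636 ± 7628 against 0.159 ± 0.0848 (13.91, adjusted p = 0.0017). Both means rest on CAB52 (replicate 7), without which the log2 fold changes were 10.65 and 9.09 and still passed (adjusted p = 0.0017 and 0.00081). With limma-voom and quality weights neither passed (log2 fold changes 5.93 and 6.97, adjusted p = 0.069 and 0.11). Prom1, a surface marker of progenitor cells, was 107-fold higher (adjusted p = 8.0e-05, log2 fold change 6.74, or 5.88 without CAB52). Cux2, on the female-biased list in which 3 of 4 measured genes rose and 1 fell, was at 52.7 ± 115 CPM against 0.782 ± 0.316 (log2 fold change 6.01, adjusted p = 0.0035, or 4.23 without CAB52). Ttn rose by 11.21 on the log2 scale (adjusted p = 0.0031), by 10.38 without CAB44, by 10.40 without CAB225 and by 3.30 without the libraries with Ttn above 1000 CPM (adjusted p = 0.0029). Its rise did not pass with limma-voom and quality weights (2.51, adjusted p = 0.15), and was 3.09 with DESeq2. Rbfox1, a splicing factor of nerve and muscle, had 0 counts in WT and was at least 951-fold higher against a floor of 3 counts over the 6 WT libraries.

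Of 11 macrophage markers 6 fell and 0 rose (adjusted p = 0.027, or 0.74 with an estimated correlation and 0.097 with the length and GC offset, which moved the median from -1.28 to -1.03), and Clec4f, specific to Kupffer cells, was at 10.6 ± 6.71 CPM against 75.1 ± 4.63. In the endothelial list 8 of 11 fell and 2 rose, with Stab2 of sinusoidal cells at -2.34 (adjusted p = 7.9e-09). Pecam1, on the same list, was higher, at 85.1 ± 9.13 CPM against 21.5 ± 3.19. In the list of stellate cells and fibroblasts 5 of 12 fell and 2 rose, with a median log2 fold change of -0.64. Without the libraries with Ttn above 1000 CPM that list was called lower (7 of 11 fell, median -1.59, adjusted p = 0.038). Lrat, of vitamin A storing stellate cells, was 6.29-fold lower (adjusted p = 1.5e-06). Of the measured markers 2 of 5 neutrophil and monocyte genes rose. Of 8 cholangiocyte genes 3 rose and 1 fell, with a median log2 fold change of -0.59. Falls were seen in 2 of 7 T and NK cell genes, 2 of 4 B and plasma cell genes and 3 of 4 erythroid genes. Of 12 subunits of SWI/SNF, the family of complexes to which Arid2 belongs, 9 rose and 1 fell. Pbrm1, a partner of Arid2 in PBAF, was 22.7-fold higher (1983 ± 447 CPM against 83.0 ± 4.15, adjusted p = 2.1e-11) and Smarca4, the ATPase, 7.52-fold higher (3.4e-10), and with the length and GC offset their log2 fold changes moved from 4.51 and 2.91 to 3.82 and 2.07. This list was called (adjusted p = 0.011, or 0.74 with an estimated correlation) and was not with the length and GC offset (adjusted p = 0.24), with which 7 rose and 4 fell. Long transcripts as a class were higher in tumours, with a median log2 fold change of 1.28 over 2502 genes with over 8000 bases of exon and -1.01 over 757 genes with up to 1000.

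**Figure D3:**
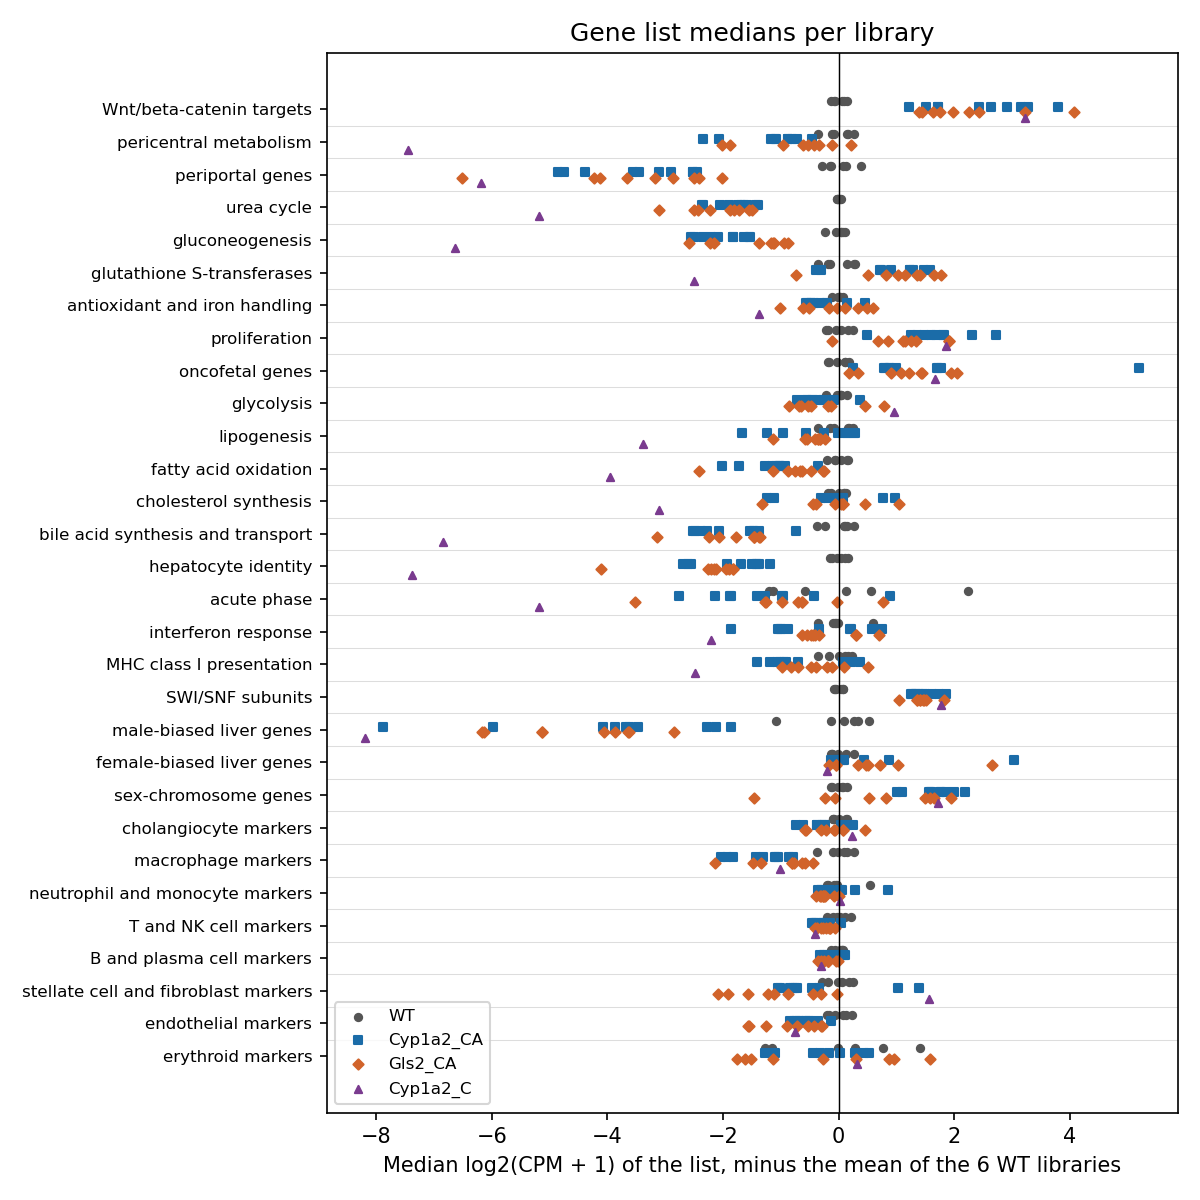
Median log2(CPM + 1) over the genes of each of the 30 lists in each library, minus the mean of that median in the 6 WT libraries, on the horizontal axis, with 1 point per library and the lists down the vertical axis. Periportal and urea cycle medians lie below all WT libraries and Wnt/beta-catenin target medians lie above them in all 20 tumour libraries, and the Cyp1a2_C library lies farthest to the left in pericentral metabolism, gluconeogenesis and hepatocyte identity.

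The comparison of Gls2_CA with WT puts the same question for tumours started from cells around the portal vein, with 5 animal numbers. Axin2 was at 306 ± 327 CPM against 11 ± 2.19, 27.1-fold higher (log2 fold change 4.76, SE 0.591, adjusted p = 1.8e-05) in 5 of 5 animals, and its log2 fold change was 3.76 without GAB235. Hal, a histidine-degrading enzyme of the periportal zone, was at 6.49 ± 4.59 CPM against 219 ± 52.1, 36.0-fold lower (-5.17, SE 0.561, adjusted p = 6.1e-06). Mki67 was 18.7-fold higher (adjusted p = 2.0e-06). Of 14976 genes tested, 10965 passed, 5870 higher and 5095 lower, and 8334 of these changed by over 2-fold, and here too the balance turned with upper-quartile factors (5118 higher and 5838 lower).

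Of 16 measured Wnt/beta-catenin targets 14 rose and 0 fell, with Tbx3 at 1.59 (adjusted p = 6.5e-05), the glutamate transporter Slc1a2 at 2.58 (6.2e-06) and the ammonium transporter Rhbg at 2.61 (9.4e-05). With the length and GC offset the values of Axin2, Tbx3 and Slc1a2 were 4.05, 0.82 and 1.41. All 14 periportal and all 8 urea cycle genes fell, with Apof 6.40-fold lower (adjusted p = 2.6e-05), Cps1 at 426 ± 289 CPM against 4601 ± 679 (4.2e-05) and Otc 6.78-fold lower (2.3e-06). In the proliferation list 15 of 18 rose and 2 fell, with Cenpf at 29.5 ± 12.7 CPM against 1.05 ± 0.209 (adjusted p = 2.6e-07). The offset moved Cenpf from 4.71 to 3.38 and Mki67 from 4.22 to 3.22. In the oncofetal list 10 of 12 rose and 0 fell, with H19 at 110 ± 183 CPM (adjusted p = 0.00025), Igf2 at 19.8 ± 32.0 (0.00055) and Prom1 90.4-fold higher (1.5e-06). Without GAB242 (replicates 4 to 6) the log2 fold changes of H19 and Igf2 moved from 9.29 and 5.68 to 7.43 and 3.92. With limma-voom and the animal number as a random effect neither passed (6.28 and 3.95, adjusted p = 0.29 and 0.22), and Igf2 missed the threshold with all 3 groups in 1 fit (adjusted p = 0.0504). The 5 lists were called with the preset correlation (adjusted p = 0.012, 0.00043, 0.0096, 0.016 and 0.043). With an estimated correlation their adjusted p was 0.90 for proliferation and 0.70 for the others. Without GAB235 the oncofetal list was not called (adjusted p = 0.12).

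Alb was at 6765 ± 3075 CPM against 58612 ± 8919 (adjusted p = 1.4e-05) and Apoa1, the main protein of high-density lipoprotein, was 6.88-fold lower (3.5e-05), in a list with 6 of 12 falls and 0 rises. Of 10 bile acid genes 6 fell and 0 rose. Of 9 male-biased genes 8 fell, with Selenbp2 at 4.40 ± 6.22 CPM against 1052 ± 364 (adjusted p = 2.0e-05) and Hsd3b5, a steroid enzyme, 163-fold lower (3.7e-05). Their log2 fold changes moved from -8.02 to -9.42 without GAB229 (replicate 2) and from -7.35 to -8.30 without GAB294 (replicates 7 to 9). Mup14 was at 0.0974 ± 0.138 CPM against 259 ± 69.8 (adjusted p = 2.6e-07, log2 fold change -11.04, or -11.74 without GAB294). Near 0 counts its fold is not firm: -12.97 with tumour counts thinned to the median WT total and -10.19 with the length and GC offset. Serpina1e, of the alpha-1-antitrypsin family, was at 15.4 ± 7.21 CPM against 12461 ± 3820 (adjusted p = 4.5e-08). Both genes belong to families whose copies share reads and differ between strains. The hepatocyte, bile acid and male-biased lists were called (adjusted p = 0.019, 0.020 and 0.0096). With an estimated correlation the adjusted p was 0.90, 0.90 and 0.70, and the bile acid list was not called with the length and GC offset (adjusted p = 0.055), where its median was -1.14 against -1.39 and 6 of 10 fell.

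In the antioxidant and iron handling list 9 of 16 rose and 3 fell. Slc7a11, the cystine carrier that feeds glutathione synthesis, was at 99.9 ± 134 CPM against 0.0533 ± 0.0483 in WT (log2 fold change 10.69, adjusted p = 0.00014, or 9.79 without GAB229). It did not pass with limma-voom and the animal number as a random effect (7.89, adjusted p = 0.13). Nqo1, a quinone reductase, was 4.64-fold higher (0.0013). Of 16 glutathione S-transferases 9 rose and 4 fell, with Gstm3 11.2-fold higher (adjusted p = 7.5e-05) and Gstp1 10.2-fold lower (9.5e-06). Inpp5j, a phosphoinositide phosphatase, was among the largest rises by the naming rule (23.5 ± 12.0 CPM against 0.0211 ± 0.0328, log2 fold change 9.80, adjusted p = 1.1e-06), with 10.44 and 10.42 without WT replicates 3 and 5. Aqp7, a glycerol channel with 0 counts in WT, was at least 423-fold higher, Cacna1b, a neuronal calcium channel, at least 727-fold and Duoxa1 at least 859-fold higher against the same floor. H2-K1 was 2.80-fold higher (adjusted p = 5.5e-05) and H2-D1 3.20-fold lower (3.9e-06), in an MHC class I list with 1 of 8 rises and 5 falls. Pericentral metabolism had 3 of 16 rises and 7 falls, gluconeogenesis 1 of 7 and 4, lipogenesis 3 of 11 and 6, fatty acid oxidation 4 of 14 and 6, cholesterol synthesis 4 of 12 and 4, glycolysis 5 of 14 and 4, acute phase 1 of 12 and 6, interferon response 2 of 13 and 5, female-biased genes 2 of 3 and 1, and sex-chromosome genes 1 of 5 and 0. Adjusted over the list alone, the only count of this comparison that differed was acute phase (5 fell). None of the lists in this paragraph was called.

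Among cell markers, 7 of 11 macrophage markers fell and 2 rose, with Clec4f at 13.5 ± 4.92 CPM against 75.1 ± 4.63, and 8 of 11 stellate and fibroblast markers fell and 1 rose, with Lrat at -2.67 (adjusted p = 2.9e-07) and Col3a1, a fibrillar collagen, at -1.81 (4.9e-06). Both lists were called (adjusted p = 0.039 and 0.016), and with an estimated correlation their adjusted p was 0.90 and 0.70. The macrophage list was not called without GAB235 (adjusted p = 0.099, 7 of 11 fell, median -1.56 against -1.66 with all animals) or with the length and GC offset (0.18, 6 fell, median -0.88), and the stellate list was not when every library counted as a replicate (0.050, just above the threshold). Endothelial markers were not called, with 8 of 11 falls and 2 rises and Stab2 5.53-fold lower (adjusted p = 1.1e-05), but were called lower with the offset (adjusted p = 0.042). Pecam1, on that list, was at 72.8 ± 24.0 CPM against 21.5 ± 3.19. Csf3r, the receptor for granulocyte colony-stimulating factor, was 10.1-fold higher (adjusted p = 1.1e-06), and of 4 measured neutrophil and monocyte genes 3 rose and 1 fell. Of 7 cholangiocyte markers 3 rose and 2 fell, of 2 T and NK cell genes and 3 erythroid genes 0 passed, and the 1 measured B cell gene fell. SWI/SNF subunits again had 9 of 12 rises and 1 fall, with Pbrm1 20.2-fold (adjusted p = 4.1e-08) and Smarca4 7.54-fold higher (8.4e-08), moved by the offset from 4.34 and 2.91 to 3.62 and 2.01 on the log2 scale. That list was called (adjusted p = 0.016, or 0.90 with an estimated correlation) and was not with the length and GC offset (0.37), with which 7 rose and 4 fell. Exon length went with the change here too, from a median log2 fold change of -1.09 over 580 genes with up to 1000 bases to 1.25 over 2395 genes with over 8000.

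The 2 tumour groups moved together against WT. Of 14968 genes tested in both, 5434 rose in both, 4710 fell in both and 0 passed in opposite directions. Independent lists of these sizes would share 2300 and 1768. Across genes, which are not independent replicates, the log2 fold changes had a Pearson correlation of 0.970 and a covariance of 3.09. Counts of tumour and WT groups were also simulated with no change, with the simulated WT columns shared and the fit not robust. They gave a mean correlation of 0.536 and a covariance of 0.0709 in 20 draws, a covariance difference of 3.02. Their 0 shared calls follow from simulating no change and add no weight. With the WT libraries split 3 and 3 between the comparisons, so that no control was shared, the correlations were 0.925 and 0.930, the covariances 3.67 and 3.67, and the shared calls in 1 direction 7898 and 7967. The depth and strain differences between tumour and WT libraries, and any difference in preparation, were common to both comparisons and enter these values.

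The direct comparison of Cyp1a2_CA with Gls2_CA asks whether tumours with the same alleles differ by the zone of the cell in which Cre acted. No gene passed. Of 17129 genes tested with edgeR 0 passed and 554 (3.23%) had an unadjusted p under 0.05, and the smallest adjusted p was 0.40. DESeq2 called 19 genes, limma-voom with quality weights 10 and edgeR on every library 6. Dnah1, a dynein of cilia, was called by all 3 of these and is named here after its values were seen. Dnah1 was at 1.25 ± 0.996 CPM in Cyp1a2_CA and 12.8 ± 7.60 in Gls2_CA (log2 fold change -3.33, SE 0.540, adjusted p = 0.40). Counts simulated with the spread of these animals gave 12% of 2-fold and 57% of 4-fold changes recovered, so smaller differences were largely not detectable with 9 and 5 animals.

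Single zonation genes showed the following values, none of which passed over all genes. Cyp1a2 was 197 ± 85.5 CPM in Cyp1a2_CA and 388 ± 213 in Gls2_CA (log2 fold change -0.97, SE 0.422), and Gls2 was 26.2 ± 21.1 and 14.2 ± 11.8 (0.89, SE 0.773). Both are also driver genes, and each had its lower mean in the group with its own CreERT2. An effect of the driver allele on these counts was not tested. Cyp2a5, a P450 with near-identical copies, was 217 ± 139 and 812 ± 639 CPM, Por, the electron donor of the P450 enzymes, 224 ± 103 and 413 ± 182, Glul, glutamine synthetase, 1655 ± 966 and 2110 ± 1013, and Lgr5, a Wnt target, 16.6 ± 8.31 and 11 ± 5.97. Otc was 100 ± 33.3 and 54.6 ± 21.1 CPM and Uroc1, of histidine breakdown, 130.5 ± 36.9 and 81.1 ± 32.9. The title letter was unbalanced, with L in 6 of 10 Cyp1a2_CA and 1 of 9 Gls2_CA libraries. With it as a covariate, in limma-voom on libraries with the animal number as a random effect, the log2 differences of Gls2 and Cyp2a5 were 0.15 and -1.16. With edgeR on summed animals they were 0.89 and -1.89, so method and unit changed here along with the letter. The lists of pericentral metabolism (7 of 16 with a positive value, adjusted p = 0.15), periportal genes (9 of 14, 0.60), urea cycle (6 of 8, 0.23) and Wnt/beta-catenin targets (6 of 18, 0.84) were not called, nor were gluconeogenesis, glutathione S-transferases, antioxidant and iron handling, oncofetal, glycolysis, lipogenesis, fatty acid oxidation, cholesterol synthesis, bile acid, acute phase, SWI/SNF, male-biased, female-biased, cholangiocyte, neutrophil and monocyte, T and NK cell, B and plasma cell, endothelial or erythroid lists.

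As sets, 7 lists were called with the preset correlation, 4 toward Cyp1a2_CA and 3 toward Gls2_CA, and 0 with an estimated correlation (adjusted p = 0.93 for each). Proliferation genes had the smallest adjusted p (3.4e-06), with 18 of 20 positive and a median log2 difference of 0.69. Ccnb2, a mitotic cyclin, was at 3.87 ± 1.53 CPM in Cyp1a2_CA and 1.62 ± 0.401 in Gls2_CA and was the 1 member past the threshold adjusted over the list alone, and Cenpf was at 54.8 ± 23.1 and 29.5 ± 12.7. All 8 MHC class I genes were negative (adjusted p = 0.0038), with Psmb8, of the immunoproteasome, at 6.02 ± 3.42 and 10.9 ± 5.21 CPM and H2-D1 at 69.0 ± 23.7 and 92.7 ± 26.4. These 2 lists were called in all 18 other fits with the preset correlation. Those fits share the animals and that correlation, so they do not stand in for the test with an estimated one. Among 60 splits of these animals, the real one included, 45 gave at least 7 called lists, so chance is not excluded for that number. Interferon response genes (12 of 13 not positive, adjusted p = 0.028) and macrophage markers (1 of 11 positive, adjusted p = 0.019, Csf1r at 66.4 ± 25.5 and 90 ± 30.5 CPM) lay toward Gls2_CA. Hepatocyte identity genes lay toward Cyp1a2_CA (11 of 12 positive, adjusted p = 0.019), with Alb at 11793 ± 8008 and 6765 ± 3075 CPM and Apoa1 at 2149 ± 1981 and 1033 ± 519. So did stellate and fibroblast markers (12 of 12 positive, adjusted p = 0.020), with Col1a2, a fibrillar collagen, whose log2 fold change of 1.10 was -0.02 without the libraries with Ttn above 1000 CPM, and Reln at 163 ± 133 and 73.1 ± 20.8, and sex-chromosome genes (3 of 5 positive, adjusted p = 0.028), with Ddx3y at 125 ± 34.6 and 73.8 ± 41.9. The other 5 were called in fewer of these 18 fits: hepatocyte in 13 (adjusted p up to 0.85, without GAB235), macrophage in 12 (0.13, without GAB242), stellate in 12, interferon in 9 and sex-chromosome in 9 (0.30, without GAB18). Without the 3 libraries with Ttn above 1000 CPM, the hepatocyte, interferon, stellate and sex-chromosome lists were not called (adjusted p = 0.24, 0.49, 0.87 and 0.057), while fatty acid oxidation (0.0034) and antioxidant and iron handling (0.015) were called lower. With the letter after the hyphen of the title as a covariate 5 lists were called, in a test that counted every library as a replicate. Hepatocyte (0.096), sex-chromosome (0.082), macrophage (0.096) and stellate (0.31) were no longer among them. Unit and method changed there along with the letter, so these losses cannot be credited to the letter alone.

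Further genes fixed by the naming rule had the following values. Hsd3b5 was at 13 ± 15 CPM in Cyp1a2_CA and 0.942 ± 1.17 in Gls2_CA, Slco1a1 at 84.6 ± 68.1 and 21.0 ± 15.9, Orm2, an acute phase protein, at 4.12 ± 4.37 and 36.7 ± 21.3, and Csf3r at 13 ± 3.55 and 20.1 ± 3.08. Orm2 and Csf3r were each the 1 member of their list past the threshold adjusted over the list alone, and over all genes Orm2 was called by DESeq2 (adjusted p = 0.038) and by limma-voom with quality weights (0.025). Gpx4, a lipid peroxide reductase, was at 106 ± 42.0 and 172 ± 74.7 CPM. Without GAB294 the log2 fold change of Hsd3b5 moved from 3.80 to 4.67. Afp was at 166 ± 483 and 3.55 ± 1.05 CPM and Igf2 at 5129 ± 13646 and 19.8 ± 32.0, and without CAB52 the log2 fold changes moved from 5.57 and 8.03 to 0.67 and 4.96, and without GAB242 that of Igf2 was 9.83.

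The Cyp1a2_C library had no replicate and was compared by its values alone. It held 113 CPM of Xist beside 92.5 CPM of the Y-linked Ddx3y, so whether it comes from 1 animal of the labelled kind is open, and its values are given with that reservation. It is also among the 4 tumour libraries with Ttn above 1000 CPM, so its values cannot be credited to its genotype. Its median over a list lay below every animal number of the other groups in 16 of 30 lists and above every one in 2, glycolysis and the stellate and fibroblast list. The hepatocyte identity median was 4.75 log2 CPM. Over animals it was 8.06 to 10.32 in Gls2_CA, 9.48 to 10.92 in Cyp1a2_CA and 12.03 to 12.33 in WT. Alb was at 297 CPM against 1973 CPM in the lowest other tumour library, GAB235-S, also with Ttn above 1000 CPM. The Wnt/beta-catenin target median, 6.77, lay within the Cyp1a2_CA range of 4.85 to 7.37, and the stellate and fibroblast median, 5.19, above the Cyp1a2_CA range of 2.65 to 5.05.

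**Figure D4:**
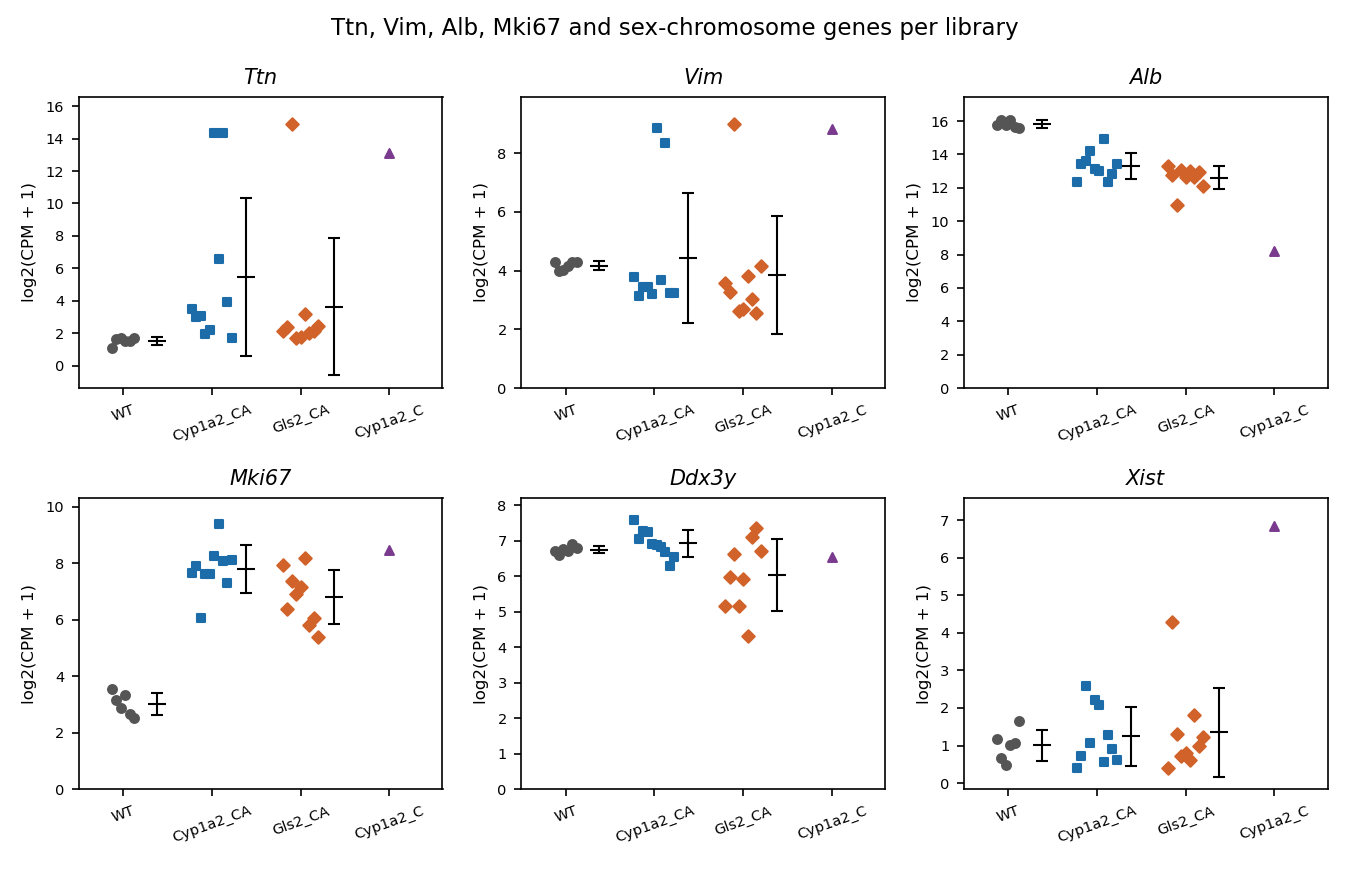
Level of Ttn, Vim, Alb, Mki67, Ddx3y and Xist as log2(CPM + 1) on the vertical axis, 1 point per library, with the mean and SD over the libraries of each replicated group. Ttn and Vim are high in 2 Cyp1a2_CA libraries, 1 Gls2_CA library and the Cyp1a2_C library, Xist is highest in Cyp1a2_C (113 CPM), and 5 Gls2_CA libraries, 2 Cyp1a2_CA libraries and Cyp1a2_C lie below every WT library in Ddx3y.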

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

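The tests of gene length, depth, preparation, muscle, cell share, driver and sex chromosomes in this part were chosen only after the results were seen, and the counts over other splits of the animals were planned.

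Of 166 groups of named genes, 9 had a highest or lowest animal far from the others by Dixon's ratio of the gap to the range, and chance gives about 1 in 20, or 8.3. In Gls2_CA, GAB235 was highest for Ctnnb1 (ratio 0.810, 323 CPM against 98.9 in the next animal) and for Smarca4 (0.876, 1138 against 735 CPM) and lowest for Inpp5j (0.946, 2.16 against 27.5 CPM). In Cyp1a2_CA, CAB26 was lowest for Cenpf (0.545, 13.9 against 40.5 CPM) and CAB52 highest for Afp (0.658, 1453 against 14.9 CPM). In WT, replicate 1 was highest for Rnf43 (0.691) and lowest for Clec4f (0.674) and Ttn (0.678), and replicate 5 was highest for Apof (0.678). In the Cyp1a2_C library, which entered no comparison, Xist, the RNA that coats an inactive X chromosome, was at 113 CPM against at most 2.13 in WT, beside 92.5 CPM of the Y-linked Ddx3y, and Ttn was at 8668 CPM against at most 2.21.

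The number of genes called between Cyp1a2_CA and WT was 11941. Only the real grouping among 60 splits gave a count this large, with 199 as the highest other, which argues against chance. A share below 1 in 60 cannot be judged from these splits. Gene length and GC as the whole cause are argued against by 81.3% of the called genes with a length being called in the same direction with an offset for both, and the lower WT depth as the whole cause by 11050 genes called after thinning. Preparation or sequencing of the WT libraries apart from the tumours cannot be told apart from the tumour effect, because the labels give no such batch and the totals of the groups do not overlap (ratio 2.18). Strain, virus and the tumour itself stay open as untested.

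Ttn was above 1000 CPM in 4 tumour libraries (CAB44-L, CAB225-L, GAB235-S and CB6-L), and 33 genes were at 100 CPM or more in all 4 and under 10 CPM in the other 22 libraries. Skeletal or heart muscle is argued against by 8 abundant muscle transcripts, Acta1 and Ckm among them, being at most 2.43 CPM there. Tnnt2, cardiac troponin T, was not among the 8 and went the other way. It was at 102 to 672 CPM, against at most 9.04 in the other tumour libraries. A lower share of hepatocytes with more of every other cell type is not decided. The macrophage and endothelial medians stayed below the highest other tumour library (largest log2 excess -0.44), while Ttn exceeded it by at least 6.53. That criterion set these lists against the excess of Ttn, which a shift in cell share need not match. An earlier criterion did not decide it either. It asked for both medians above the median of the others (0 of 4) or a median below every other (0 of 4). Stromal markers did go up, with Dcn at 73.0 to 197 CPM against at most 67.3 in the other tumour libraries and the stellate and fibroblast median above all of these in CAB44-L, CAB225-L and CB6-L, and Apob was lower (129 to 3986 against at least 5954 CPM), so a change in mesenchymal cells stays open. The driver as the whole cause is argued against by 1 such library among Gls2_CA tumours. That rests on 1 animal and was known when the question was put, so it adds nothing beyond the values. A tumour type that arises under both drivers may be behind these libraries, a hypothesis the labels do not let one test.

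In 5 Gls2_CA libraries of GAB18, GAB229 and GAB242, Ddx3y (18.8 to 62.0 CPM) and Kdm5d (4.76 to 11.3) lay below all WT libraries (at least 96.4 and 18.6), while Uty (45.1 to 128) lay above them (at most 37.2) and Eif2s3y (11.6 to 60.1) on both sides (38.6 to 48.4). Other tumour libraries lay below WT too, less far in Ddx3y (77.0 CPM in CAB228-M, 91.8 in CAB239-M and 92.5 in CB6-L) and farther in Kdm5d (down to 1.31 CPM in CAB52-L). Female cells in these tumours are argued against by 4 of the 5 having Xist at or below the highest WT library, and GAB229 had 18.5 CPM of Xist. An inherited Y chromosome of the other strain as the whole cause is argued against by the libraries of GAB242. They differed by at least 2.37 times in each of 4 Y-linked genes, against at most 1.25 times between WT libraries. The libraries of GAB294, also tumours of 1 animal number, differed by 1.16 to 1.58 times. Such a Y chromosome with variation between tumours added stays open. The mean pairwise correlation of the 4 genes over 14 tumour animals (0.58) was at the 99.6th percentile of 10000 random sets. Kdm5d was less correlated (0.16 to 0.49) than the other 3 (0.70 to 0.90). Against other tumours, the 5 libraries lay below every one in Eif2s3y (at most 60.1 against at least 68.9 CPM). Their Uty reached 128 CPM, against 214 to 277 in the other Gls2_CA libraries and at least 128 in Cyp1a2_CA. Loss of the Y chromosome from part of the tumour cells stays open. Uty above all WT libraries does not decide against a loss relative to WT. WT also differs from the tumours in strain, and long transcripts as a class were higher in tumours. Uty has 9791 bases of exon, but Kdm5d, with 15164, lay below WT in these libraries.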

How the results depend on the processing

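The fits without the libraries with Ttn above 1000 CPM, with an offset for length and GC and with thinned counts, the title-letter list test and the count of fry calls were chosen after the data were seen.

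No gene passed between Cyp1a2_CA and Gls2_CA with edgeR (554 at an unadjusted p under 0.05), against 19 with DESeq2, 10 with limma-voom and quality weights and 6 with every library as a replicate, and the count was 0 without each animal in turn (0 to 0). The cause was not tested. Gene lists called were 0 with an estimated correlation in all 3 comparisons. With fry, which asks another question, they were 0 for Cyp1a2_CA against Gls2_CA, 23 for Cyp1a2_CA against WT and 19 for Gls2_CA against WT, and with the offset 5 for Cyp1a2_CA against WT. Leaving out animals gave 3 lists without CAB44, 4 without CAB225 and up to 9 for Cyp1a2_CA against Gls2_CA, 9 to 10 for Cyp1a2_CA against WT and 9 to 11 for Gls2_CA against WT.

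Genes called without each animal were 11497 to 12004 for Cyp1a2_CA against WT and 10694 to 11879 for Gls2_CA against WT, and other alternatives gave 10161 to 12910 and 9620 to 12153. Of 2838 values of named genes, 2796 kept direction and side of the threshold, 20 lost the call, 13 gained it and 9 reversed. Ctnnb1 between Cyp1a2_CA and Gls2_CA was -0.00911 with the first library of each animal and -0.12 to 0.71 without each animal, and Col1a2 was -0.0188 without the libraries with Ttn above 1000 CPM, neither called in any fit. With the offset 33 of 76 values against WT moved by over 1.5 times, Arid2 in Cyp1a2_CA to -2.23 among them, and all 33 kept their direction and call. No paired analysis was possible because replicate numbers only name libraries and no animal is in 2 groups. Not run were the random effect for Cyp1a2_CA against WT (not estimable from 1 pair of libraries) and sex as a covariate (its condition, both sexes in both groups, was not met, since all libraries held Y-linked transcripts). The lower WT depth limits low genes most.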

Other observations

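The values and tests in this part were chosen only after the results were seen, apart from the counts over other splits of the animals, which were planned.

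The 4 libraries with Ttn above 1000 CPM shared further genes. T (brachyury), a transcription factor of the early embryo, was at 249 CPM in CAB44-L, 317 in CAB225-L, 545 in GAB235-S and 29.7 in CB6-L against at most 1.53 in the other tumour libraries. Vim, the mesenchymal intermediate filament, was at 324 to 514 CPM against at most 16.8. Stra6, a retinol receptor, was at 331 to 1654 CPM against at most 3.07, and Tnnt2, cardiac troponin T, at 102 to 672 against at most 9.04. Among Wnt pathway genes, Lef1 was at 236 to 467 CPM against at most 36.0, Wif1 at 155 to 410 against at most 4.24, Nkd1 at 269 to 557 against at most 159 and Axin2 at 534 to 889 against 85.3 to 416. Apob was at 129 to 3986 CPM against at least 5954 in the other tumour libraries, and Glul was at 110 to 703 against 388 to 6190. The matrix genes differed within the 4, with Col1a1 at 659 CPM in CB6-L and 19.6 in GAB235-S.

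Several long and abundant transcripts were higher in every tumour library than in every WT library. Zbtb20, a transcriptional repressor of Afp, was at 11567 to 23272 CPM in the Cyp1a2_CA libraries, 11356 to 18463 in Gls2_CA and 839 to 1047 in WT, and Ncor1, a nuclear receptor corepressor, at 4057 to 7730, 3975 to 6811 and 236 to 272 CPM. Huwe1 was at 3460 to 7269, 3745 to 6134 and 439 to 488 CPM, and Dst at 2146 to 16192, 4404 to 12080 and 229 to 297. With 30730, 12811, 23507 and 41155 bases of exon these 4 belong to the length class that was higher in tumours as a whole, and no explanation was tested for them alone. Eif4g1, with 7301 bases, was at least at 1699 CPM in tumours and at most at 713 in WT.

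In the other splits of the animals, lists were called about as often as in the real grouping: 45 of 60 splits gave at least the 7 lists of Cyp1a2_CA against Gls2_CA (highest other 15), 35 of 60 the 9 of Cyp1a2_CA against WT (17) and 26 of 60 the 11 of Gls2_CA against WT (15), so chance is not excluded for the numbers of lists. For genes between Cyp1a2_CA and Gls2_CA the real count was 0 with edgeR (554 at an unadjusted p under 0.05, 19 called by DESeq2 and 10 by limma-voom with quality weights), which every split must reach (60 of 60), so the splits decide nothing there. The highest other count, 2076, came from a split that put all 3 animals with Ttn above 1000 CPM into the group of 5, a structure of the samples. For Gls2_CA against WT only the real grouping among 60 splits reached its count, which argues against chance as far as 60 splits can show. The highest other (8159 genes against 10965) was nearly the mirror of the real one, with 1 WT animal among the 5 tumour animals.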
